A study of Homo sapiens with 56 samples.

How the data were processed

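Gene expression was measured by bulk RNA sequencing in Mv4;11 and KG-1, 2 established human acute myeloid leukaemia cell lines. Per the labels' protocols, cells received PMR-116 or CX-5461 at 1 µM, or the vehicle, for 3 h or 12 h. Both compounds inhibit RNA polymerase I, the enzyme that transcribes the large ribosomal RNA precursor. The vehicle was a citrate and phosphate buffer. Each compound had its own vehicle libraries at each time, so no vehicle library entered the comparisons of both compounds. The labels placed 56 libraries in 16 groups, 4 libraries in each of the 8 KG-1 groups and 3 in each of the 8 Mv4;11 groups. Total RNA was isolated with the Nucleospin RNA kit and libraries were made with the Illumina Stranded mRNA Prep kit, per the labels' protocols. That kit selects polyadenylated RNA, so the ribosomal RNA precursor itself was not measured.

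The deposited tables held estimated counts per gene symbol, 1 table per cell line. The submitters' processing notes name Salmon 1.5.2, which estimates transcript abundance, DESeq2 and the genome build GRCh38.p13, without giving their roles. The annotation release and the strand setting of the counting are not given in the sources used here. The name of the KG-1 table in the labels mentions trimming and that of the Mv4;11 table does not. Of the deposited values above 0, 100.0% were not whole numbers (within 1e-06) in each table, the form that estimated counts take. There were 59409 symbols for Mv4;11 and 59081 for KG-1, all of the latter among the former. Every entry named a gene. The Mv4;11 table had 24 further columns that matched no sample of the labels, and these were not used here. Library totals ranged from 31010467 to 72707768 in KG-1 and from 28751951 to 41542587 in Mv4;11. Between 21945 and 25086 genes per library had a count in KG-1, and between 27765 and 31395 in Mv4;11.

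The estimated counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 18618 genes in KG-1, 20495 in Mv4;11 and 23759 in a joint fit of both lines. Library sizes were scaled with the trimmed mean of M-values (TMM). The 8 groups of a line were fitted together with estimateDisp, glmQLFit and glmQLFTest, so that all groups of a line shared 1 estimate of the spread. Effects were compared between lines in the joint fit of 16 groups. Each compound was compared with its own vehicle, PMR-116 with CX-5461 as a difference of their effects, 12 h with 3 h as a difference of effects, and Mv4;11 with KG-1 as a difference of effects. The vehicle groups of both compounds were compared with each other. All tests were 2-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. In the text, adjusted p for a gene is from edgeR's quasi-likelihood test. Errors after ± are standard errors of the log2 fold change unless named otherwise, obtained from the fold change and its F statistic, and 95% intervals are log2 fold changes with normal quantiles. CPM are counts scaled to the TMM-adjusted library size.

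Members of 26 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 with its preset correlation of 0.01, where 5 or more members were tested, and adjusted over the lists of a comparison. The lists reported were cytosolic ribosomal proteins, ribosome biogenesis factors, RNA polymerase I machinery, MYC target genes, DNA replication and G1/S genes, G2/M and mitosis genes, replication-dependent histone genes, integrated stress response (ATF4) genes, unfolded protein response genes, heat shock genes, NF-kB and inflammatory cytokine genes, interferon-stimulated genes, immediate-early genes, cholesterol synthesis genes (with related lipid genes), lysosome and autophagy genes, DNA damage response and repair genes, apoptosis regulators of the BCL2 family, snoRNA host genes, monocyte and granulocyte differentiation genes, haematopoietic stem cell and leukaemia genes, erythroid and megakaryocyte markers, lymphocyte markers, fibroblast, endothelial and epithelial markers, mitochondrially encoded mRNAs, and ribosomal RNA features. The last list had too few tested members in KG-1. An adjusted p for a list is from camera unless said otherwise, and a value with an estimated correlation is from camera with the correlation between genes estimated per list. The MYC list shared 2 genes with the heat shock list.

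The genes named in the text were set by a rule fixed before the data were examined. For each compound against vehicle these were the 8 largest rises and the 8 largest falls among protein-coding genes with an adjusted p under 0.05, a mean of 5 CPM or more in the higher group, and every treated library above (or below) every vehicle library. Chance alone gives such a separation for 10% of genes with 3 libraries against 3 and 2.86% with 4 against 4. For differences of effects, the 4 largest in each direction were taken without the last condition. MYC, CDKN1A, MDM2, UBTF, RRN3, POLR1A and POLR1B were always included, as were the 4 members of each list with the lowest adjusted p. A few genes and 1 gene list are not reported here. Biotypes and mitochondrial gene positions were taken from GENCODE release 29 on GRCh38, which held 54390 of the Mv4;11 symbols and 54087 of the KG-1 symbols.

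The fits were tested on simulated counts, drawn with the real means, dispersions and library sizes and with 200 genes changed. For KG-1 at 3 h of PMR-116, 70.4% of 98 simulated changes of 1 log2 unit and 42.1% of 95 changes of 0.5 units were called. For Mv4;11 at 3 h of PMR-116 the shares were 67.7% of 99 and 41.7% of 96. For the difference between compounds at 3 h in Mv4;11 they were 58.6% of 99 and 17.7% of 96, and for the difference between the lines at 3 h of PMR-116 38.4% and 26.3% of 99 each. Camera called only the shifted list, but correlation between genes was not simulated.

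Alternatives were DESeq2 1.42.0, size factors of the relative log expression (RLE) type, no filter on low counts, the replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Gene lists were also tested with an estimated correlation, with fry, with RLE factors, with the block and without each library. Scaling by library totals alone, and leaving out 1 Mv4;11 vehicle library that stood apart, were added after the data were seen. No spike-in was used here, so all changes are relative to the bulk of the RNA measured. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Each line lies in its own table, and the KG-1 labels name a batch that the Mv4;11 labels do not, so line and batch cannot be told apart. Antisense genes, histone genes and other near-identical families are uncertain, because the counting may have divided shared reads between copies.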

Results

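The transcriptomes of 56 libraries were examined, 32 from KG-1 and 24 from Mv4;11. Both are human acute myeloid leukaemia lines grown in suspension. Each line was sampled after 3 h and 12 h with 1 µM PMR-116 or 1 µM CX-5461, and beside each compound with its own vehicle, with 4 libraries per group in KG-1 and 3 per group in Mv4;11. Total counts per library were 31010467 to 72707768 in KG-1 and 28751951 to 41542587 in Mv4;11. The correlation of log2 CPM between replicates of a group was between 0.980 and 0.990. The 1 library at the lowest value was replicate 3 of the vehicle for PMR-116 at 12 h in Mv4;11, which held 438 CPM of RN7SL2 against 9.18 to 15.8 CPM in the other 5 vehicle libraries of that time, 1126 CPM of MALAT1 against 59.4 to 73.6, and 2607 CPM of MT-RNR1 against 320 to 365. These are abundant noncoding RNAs, and values without that library are given where it bears on a gene group. No pair of replicate libraries agreed within sampling noise (lowest chi-square per degree of freedom 7.03).

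Each compound was compared with its vehicle to ask which genes respond to inhibition of RNA polymerase I in each line. In Mv4;11, 4939 of 20495 tested genes changed after 3 h of PMR-116 (2253 higher, 2686 lower) and 8859 after 12 h (4241 higher, 4618 lower). CX-5461 changed 2390 genes after 3 h (1036 higher, 1354 lower) and 6430 after 12 h (3042 higher, 3388 lower). In KG-1, 1364 of 18618 tested genes changed after 3 h of PMR-116 (673 higher, 691 lower) and 1762 after 12 h (880 higher, 882 lower), and CX-5461 changed 640 (345 higher, 295 lower) and 473 (254 higher, 219 lower). Changes of 2-fold or more were 916 and 2464 genes for PMR-116 in Mv4;11 at 3 h and 12 h, and 125 and 108 in KG-1. For CX-5461 they were 387 and 1055 in Mv4;11 and 29 and 19 in KG-1. Scaling by library totals in place of TMM moved the median log2 fold change of all genes to 0.188 for PMR-116 and 0.114 for CX-5461 at 12 h in Mv4;11, from 0.023 and 0.034, so small changes there are relative to that shift. With library totals the calls at 12 h in Mv4;11 were 6275 higher and 3203 lower for PMR-116 and 4086 and 2591 for CX-5461. Those of PMR-116 at 3 h in Mv4;11 were 2877 and 2251, and those at 3 h in KG-1 552 and 885 for PMR-116 and 308 and 419 for CX-5461. Leaving out 1 library lowered a count by more than 1.5 times for PMR-116 at 3 h in KG-1 (901 without vehicle replicate 2) and CX-5461 at 3 h in Mv4;11 (1573 without treated replicate 3). It did so too for CX-5461 in KG-1 at 3 h (362 to 380 without treated replicate 1 or 2 or vehicle replicate 2, 3 or 4) and 12 h (288 to 311 without treated replicate 1 or 2 or vehicle replicate 3 or 4). Without the Mv4;11 vehicle library that stood apart, 8375 genes changed at 12 h of PMR-116.

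**Figure D1:**
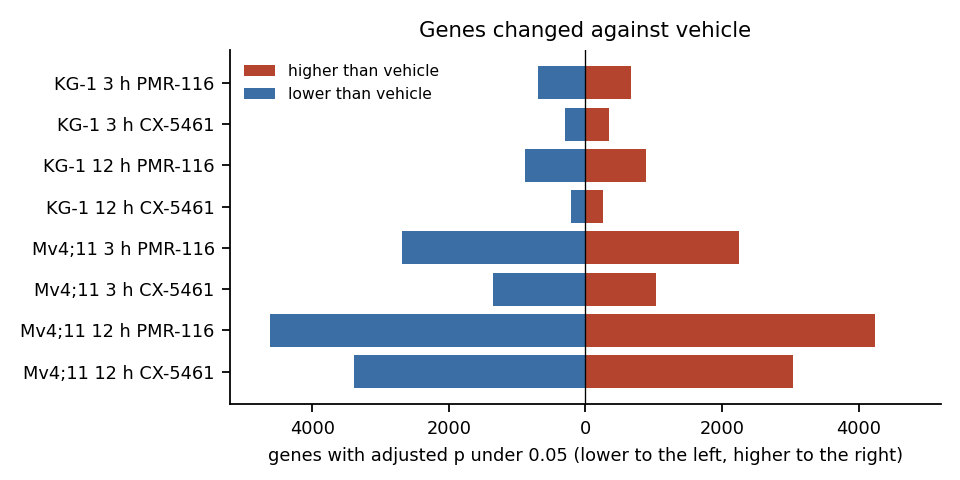
Number of genes higher (right) or lower (left) than the matched vehicle at an adjusted p under 0.05, for each line, time and compound (3 libraries per group in Mv4;11, 4 in KG-1). Bars run from 473 genes in total for CX-5461 at 12 h in KG-1 to 8859 for PMR-116 at 12 h in Mv4;11.

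After 3 h of PMR-116 in Mv4;11, CDKN1A and MDM2 rose and MYC fell (n = 3 libraries per group). CDKN1A, which encodes the cell cycle inhibitor p21, stood at 645 ± 18.7 against 114 ± 12.1 CPM (mean ± SD), a log2 fold change of 2.50 ± 0.10 (adjusted p = 1.56e-14). MYC, a transcription factor that drives growth and ribosome production, stood at 120 ± 21.8 against 487 ± 8.34 CPM, a log2 fold change of -2.03 ± 0.09. MDM2, an E3 ubiquitin ligase, rose by 1.20 ± 0.12, as did the death receptor TNFRSF10B (1.52 ± 0.06). The largest rises by the naming rule were FAM71F2 (2.74 ± 0.42), SPTBN5 (2.71), the cytokine LIF (2.69 ± 0.26), CDKN1A, the polo-like kinase PLK2 (2.39 ± 0.12), SESN2 (2.39 ± 0.12), a stress-induced inhibitor of mTORC1, EFCAB12 (2.28) and the actin gene ACTA2 (2.25 ± 0.26). The largest falls were MYC, HPDL (-2.03 ± 0.15), the transcription factor NFE2 (-2.0 ± 0.12), the chemokine receptor CCR6 (-1.99), the homeobox gene DLX1 (-1.70), the glucose transporter SLC2A3 (-1.64), GBGT1 (-1.63) and KBTBD11 (-1.62).

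Members of the gene lists were counted over all genes tested and, in square brackets, adjusted over the list alone. Where a call ended with 1 library left out, that library (treated or vehicle, with its replicate number) and the highest adjusted p without it are given. Lists tied to ribosome production and growth were lower. There, 71 of 106 ribosome biogenesis factors fell and 2 rose [78 and 3], among them PPAN (-0.88 ± 0.06) and the RNA acetyltransferase NAT10 (-0.88), 10 of 21 genes of the RNA polymerase I machinery fell and 0 rose [11 and 3], and 27 of 53 MYC target genes fell and 0 rose [29 and 1], among them the folate carrier SLC19A1 (-1.30) and hexokinase HK2 (-0.98). These 3 sets had an adjusted p of 3.43e-26, 0.000639 and 6.2e-10, and with an estimated correlation the adjusted p was 0.161, 0.248 and 0.248. POLR1A, the largest subunit of the enzyme, fell (-0.47 ± 0.08, adjusted p = 0.000135), as did POLR1B (-0.81), POLR1G (-1.23) and UBTF (-0.17), which binds the ribosomal DNA promoter. RRN3, which recruits the polymerase, was at -0.16 ± 0.07 (adjusted p = 0.106). The call of UBTF ended without 1 library (treated 2 and 3, vehicle 2, 0.085).

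Among the other lists at 3 h of PMR-116 in Mv4;11, 15 of 35 immediate-early genes rose and 2 fell [18 and 2], with ATF3 at 1.79, 16 of 29 cholesterol synthesis genes fell and 1 rose [19 and 1], including SQLE (-0.79), and 10 of 26 snoRNA host genes fell and 1 rose [12 and 1]. Of the stem cell and leukaemia genes, 13 of 27 fell and 3 rose [13 and 3], including SOX4 (-0.94) and MYB (-0.40). These 4 sets had an adjusted p of 2.17e-08, 2.34e-06, 6.68e-06 and 5.12e-05, and with an estimated correlation the adjusted p was 0.0746, 0.282, 0.0746 and 0.0746. Further, 21 of 44 ATF4 genes fell and 5 rose [24 and 5], 14 of 35 unfolded protein response genes fell and 1 rose [14 and 2], with HERPUD1 at -1.24, and 21 of 66 G2/M and mitosis genes fell and 1 rose [21 and 1] (adjusted p = 0.000392, 0.00127 and 0.0042). With an estimated correlation their adjusted p was 0.426, 0.404 and 0.638, and the call of the G2/M genes ended without 1 library (vehicle 1, 0.074). Of the monocyte and granulocyte genes, 8 of 34 fell and 2 rose [8 and 2], with CSF1R (-0.58) lower and NCF1 (0.87) higher (adjusted p = 0.00862, and adjusted p = 0.316 with an estimated correlation). Of the mitochondrially encoded mRNAs, 9 of 13 fell and 1 rose [10 and 1] (adjusted p = 8.49e-06, and adjusted p = 0.332 with an estimated correlation).

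Lists not called as sets in this comparison were DNA replication and G1/S genes (adjusted p = 0.39), heat shock genes (0.39), NF-kB and cytokine genes (0.122), interferon-stimulated genes (0.516), cytosolic ribosomal proteins (0.535), histone genes (0.656) and BCL2 family regulators (0.947, with a median of -0.09 but a mean of 0.05 and a test in the direction of the mean). Of these, ribosomal proteins were called without vehicle replicate 3 (adjusted p = 0.0167) and replication genes without vehicle replicate 1 (0.0461). Markers of other cell types were also not called, with adjusted p values of 0.597 for erythroid and megakaryocyte, 0.757 for lymphocyte and 0.535 for fibroblast, endothelial and epithelial genes. Of the ribosomal RNA features, 2 of 5 rose and 0 fell [2 and 0], with a median of -0.50, a mean of 0.15 and a test in the direction of the mean (adjusted p = 0.375).

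CX-5461 for 3 h in Mv4;11 raised CDKN1A and MDM2 and lowered mitotic genes (n = 3 per group). CDKN1A stood at 1176 ± 89.2 against 108 ± 12.1 CPM, a log2 fold change of 3.44 ± 0.10 (adjusted p = 2.72e-17), and MDM2 rose by 2.13 ± 0.12. MYC stood at 168 ± 13.4 against 481 ± 11.6 CPM, a log2 fold change of -1.52 ± 0.09. Among the largest rises were GDF15 (5.30 ± 0.40), a stress-induced cytokine, BAIAP3 (4.74 ± 0.63), LIF (4.31 ± 0.28), the adhesion gene NECTIN4 (3.87 ± 0.26), CDKN1A, the death receptor FAS (2.46) and SESN2 (2.45). The largest falls were the DNA helicase PIF1 (-1.95 ± 0.19), HPDL (-1.65), MYC, the cystine transporter SLC7A11 (-1.47), CACNA2D3 (-1.41), PYCR3 (-1.40), the mitotic kinesin KIF20A (-1.38 ± 0.09) and NFE2L3 (-1.32). POLR1A (-0.25, adjusted p = 0.04), POLR1B (-0.36, 0.0353) and RRN3 (-0.29) were lower, and UBTF was at 0.03 ± 0.05 (adjusted p = 0.789). Calls that ended without 1 library were POLR1A (any 1 library but treated 2, 0.178), POLR1B (treated 1 and 3, vehicle 2 and 3, 0.182), RRN3 (treated 3, 0.0561) and SLC7A11 (treated 3, vehicle 1, 0.109).

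Of the gene lists, 58 of 66 G2/M and mitosis genes fell and 0 rose [61 and 0], with a median of -0.58 (brackets adjusted over the list alone), including KIF23 (-1.06), CCNF (-0.99) and UBE2C (-0.99). This set was called and held with an estimated correlation (adjusted p = 1.4e-85, and adjusted p = 0.000531 with an estimated correlation). Further, 51 of 106 ribosome biogenesis factors fell and 2 rose [68 and 3], 8 of 21 genes of the RNA polymerase I machinery fell and 1 rose [9 and 2], and 15 of 53 MYC target genes fell and 0 rose [16 and 1] (adjusted p = 2.14e-17, 0.0279 and 3.03e-05). With an estimated correlation the adjusted p of these 3 sets was 0.28, 0.452 and 0.452, and the call of the RNA polymerase I machinery ended without 1 library (treated 3, vehicle 2, 0.084). Of the unfolded protein response genes 10 of 35 fell and 0 rose [12 and 0]. Of the stem cell and leukaemia genes 8 of 27 fell and 1 rose [9 and 1], with the receptor kinase FLT3 at -0.50. Of the snoRNA host genes 7 of 26 fell and 0 rose [9 and 0]. These 3 sets had an adjusted p of 3.03e-05, 6.2e-05 and 0.00211, and with an estimated correlation 0.324, 0.109 and 0.242. Of the DNA damage response genes 8 of 51 fell and 2 rose [14 and 2]. Of the immediate-early genes 5 of 35 rose and 3 fell [6 and 4]. These 2 sets had an adjusted p of 0.018 and 5.97e-05, and with an estimated correlation 0.452 and 0.242. Sterol synthesis genes (adjusted p = 0.183), DNA replication genes (0.64) and mitochondrial mRNAs (0.205) were not called. Sterol synthesis genes were called without treated replicate 1 (adjusted p = 0.0371).

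**Figure D2:**
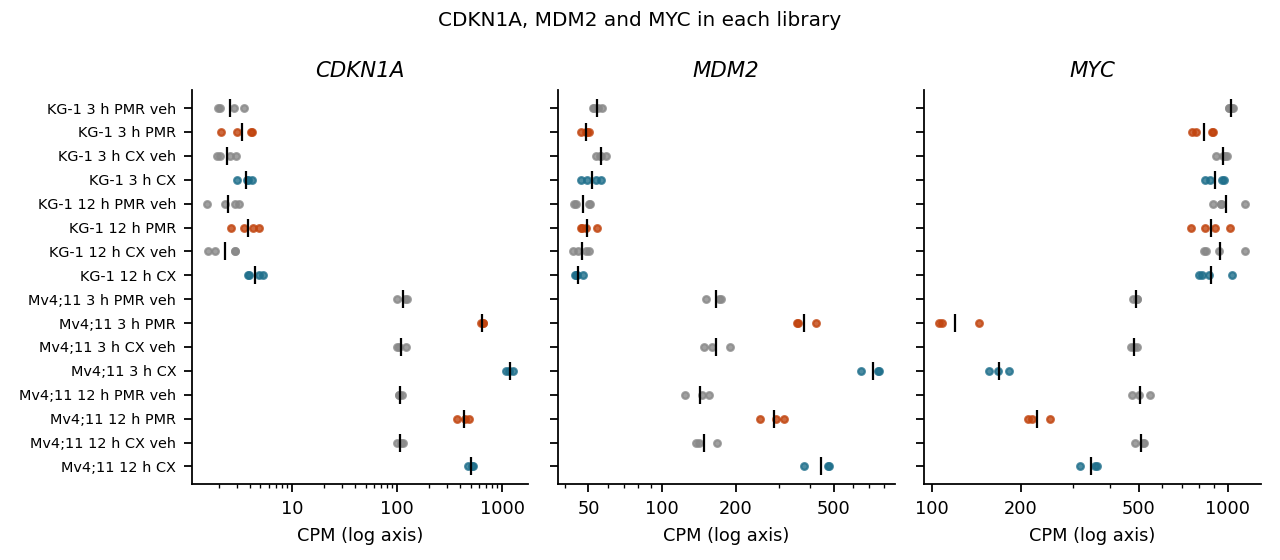
CDKN1A, MDM2 and MYC in each library, in CPM on log axes, with 1 dot per library (vehicle grey, PMR-116 orange, CX-5461 blue) and a tick at each group mean. CDKN1A means ran from 106 to 114 CPM in the vehicles of Mv4;11 and from 432 to 1176 CPM with a compound.

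At 12 h of PMR-116 in Mv4;11, genes of DNA replication, MYC targets and sterol synthesis had fallen and CDKN1A was still higher (n = 3 per group). MCM2, a subunit of the replicative helicase, stood at 109 ± 3.75 against 474 ± 23.3 CPM, a log2 fold change of -2.12 ± 0.05, and CDKN1A stood at 432 ± 56.9 against 106 ± 3.52 CPM (2.03 ± 0.09). MYC was at 227 ± 21.2 against 505 ± 36.1 CPM (-1.16 ± 0.09) and POLR1A at 84.0 ± 2.97 against 170 ± 14.8 CPM (-1.02 ± 0.08). Among the largest rises were the histone genes H2AC6 (4.60 ± 0.32) and H4C15 (3.91 ± 0.54), the lysosomal nuclease DNASE2 (3.63 ± 0.21), the costimulatory receptor CD86 (3.61 ± 0.30), haem oxygenase HMOX1 (3.24), the receptor kinase AXL (3.20) and UNC13A (3.11). The largest falls were ALDH1L2 (-3.37 ± 0.30), a mitochondrial folate enzyme, DHCR7 (-3.34), which makes cholesterol in its last step, HPDL (-3.21), the amino acid transporter SLC38A5 (-3.16), the fatty acid desaturases FADS2 (-3.07) and SCD (-2.77), the uracil DNA glycosylase UNG (-3.03) and RPL22L1 (-2.70). POLR1B (-0.98), RRN3 (-0.32) and UBTF (-0.35) fell and MDM2 rose (1.01).

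Of the DNA replication and G1/S genes, 56 of 56 fell and 0 rose [56 and 0], with a median of -1.48 (brackets adjusted over the list alone). Also lower were MYC targets, where 51 of 53 fell and 0 rose [51 and 0], among them the purine enzyme PAICS (-1.84) and CDK4 (-1.40), and cholesterol synthesis genes, where 27 of 29 fell and 1 rose [27 and 1]. Further, 100 of 106 ribosome biogenesis factors fell and 0 rose [101 and 0], 17 of 21 genes of the RNA polymerase I machinery fell and 0 rose [17 and 0], 39 of 51 DNA damage response genes fell and 5 rose [39 and 5], including the kinase CHEK1 (-1.78), and 19 of 23 heat shock genes fell and 0 rose [19 and 0], including HSPA8 (-1.83). Higher were interferon-stimulated genes, where 29 of 42 rose and 0 fell [29 and 0], including STAT2 (1.29) and HERC5 (1.31), and NF-kB and cytokine genes, where 14 of 30 rose and 3 fell [14 and 3]. In this order these 9 sets had an adjusted p of 2.6e-112, 1.2e-54, 8.53e-28, 2.67e-40, 1.29e-07, 4.76e-19, 7.91e-16, 1.82e-08 and 0.00401. With an estimated correlation all 9 were still called (adjusted p = 0.000607, 0.00268, 0.00532, 0.0319, 0.0319, 0.00268, 0.0333, 0.0136 and 0.0333).

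Other lists were called at 12 h of PMR-116 in Mv4;11 with the preset correlation but not with an estimated one. Of the G2/M genes 52 of 66 fell and 0 rose [52 and 0]. Of the ATF4 genes 31 of 44 fell and 5 rose [32 and 5], including the serine enzyme PSAT1 (-2.41). Of the unfolded protein response genes 23 of 35 fell and 3 rose [24 and 3]. Of the snoRNA host genes 14 of 26 fell and 2 rose [15 and 2]. These 4 sets had an adjusted p of 3.54e-12, 1.85e-13, 1.29e-07 and 0.00305, and with an estimated correlation 0.0973, 0.0614, 0.0973 and 0.0973. Of the lysosome genes 25 of 38 rose and 3 fell [25 and 3], including the cathepsin CTSB (1.21). Of the immediate-early genes 15 of 35 rose and 4 fell [15 and 4]. Of the monocyte and granulocyte genes 16 of 34 rose and 7 fell [18 and 8], with the phagocyte oxidase subunit NCF1 at 2.32. These 3 sets had an adjusted p of 5.47e-07, 3.69e-05 and 0.00286, and with an estimated correlation 0.0651, 0.0973 and 0.135. Of the replication-dependent histone genes, 15 of 34 rose and 5 fell [16 and 6], with H2AC11 at 2.72 (adjusted p = 0.000335, and adjusted p = 0.297 with an estimated correlation). These transcripts are mostly not polyadenylated and the gene copies are near-identical, so single members are uncertain. Of the mitochondrial mRNAs, 12 of 13 fell and 1 rose [12 and 1] (adjusted p = 1.85e-09, and adjusted p = 0.0973 with an estimated correlation), and the adjusted p was 3.26e-16 without the vehicle library that stood apart. Of the cytosolic ribosomal protein genes, 26 of 78 fell and 0 rose [24 and 0], and the set was not called (adjusted p = 0.0971). It was called without treated or vehicle replicate 3 (adjusted p at most 0.0298). Nor were BCL2 family regulators (adjusted p = 0.229), stem cell and leukaemia genes (0.41), and markers of erythroid and megakaryocyte (0.924), lymphocyte (0.63) and fibroblast, endothelial and epithelial cells (0.116). Of the ribosomal RNA features, 3 of 5 fell and 1 rose [3 and 1], with a median of -1.48 and a mean of -0.68 but a test in the upward direction (adjusted p = 0.937). The falls of its members rested on the vehicle library that stood apart, without which RNA5-8SN1 was at -0.52 (adjusted p = 0.0644) and the set was called in the upward direction (0.0437). The copies RNA5-8SN1, RNA5-8SN2 and RNA5-8SN3 held identical values and are 1 measurement.

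With CX-5461 for 12 h in Mv4;11, genes of DNA replication, mitosis, MYC targets and sterol synthesis fell and CDKN1A rose (n = 3 per group). MCM2 stood at 178 ± 3.27 against 474 ± 14.3 CPM (-1.41 ± 0.05), CDKN1A at 503 ± 28.7 against 108 ± 6.63 CPM (2.23 ± 0.09) and MYC at 344 ± 23.6 against 507 ± 20.3 CPM (-0.56 ± 0.09). Among the largest rises were UNC13A (4.92 ± 0.29), KANK3 (3.84), AXL (3.38), cytoglobin CYGB (3.22), DQX1 (3.15), NECTIN4 (2.92) and the immunoglobulin E receptor gene FCER1A (2.87). The largest falls were PHGDH (-2.91 ± 0.18), the first enzyme of serine synthesis, ALDH1L2 (-2.37), BCAT1 (-2.35), a branched-chain aminotransferase, TBC1D30 (-2.27), FADS2 (-2.20), SCD (-2.19), HPDL (-1.93) and the adenylate kinase AK4 (-1.85). POLR1A (-0.32), POLR1B (-0.50) and UBTF (-0.17, adjusted p = 0.0138) fell, and MDM2 rose (1.58). The call of UBTF ended without 1 library (treated 3, vehicle 2, 0.0795).

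Of the DNA replication and G1/S genes, 56 of 56 fell and 0 rose [56 and 0], with a median of -1.05 (brackets adjusted over the list alone). Further, 63 of 66 G2/M genes fell and 0 rose [65 and 0], 47 of 53 MYC target genes fell and 0 rose [48 and 1], 26 of 29 cholesterol synthesis genes fell and 1 rose [26 and 1], and 41 of 51 DNA damage response genes fell and 3 rose [41 and 3]. Of the heat shock genes 18 of 23 fell and 0 rose [18 and 0]. Of the ATF4 genes 32 of 44 fell and 3 rose [33 and 5]. Of the RNA polymerase I machinery 17 of 21 fell and 0 rose [17 and 0]. Higher were interferon-stimulated genes, where 27 of 42 rose and 0 fell [29 and 0], and NF-kB and cytokine genes, where 10 of 30 rose and 3 fell [12 and 3]. These 10 sets had, in this order, an adjusted p of 1.52e-103, 3.44e-38, 7.3e-39, 1.74e-29, 7.36e-22, 5.81e-14, 6.52e-16, 4.77e-06, 1.91e-09 and 0.00652. All 10 held with an estimated correlation (adjusted p = 0.000468, 0.00617, 0.00518, 0.00511, 0.00107, 0.0441, 0.0441, 0.0445, 0.00617 and 0.0441). Not so held were ribosome biogenesis factors, where 84 of 106 fell and 0 rose [90 and 0], unfolded protein response genes, where 16 of 35 fell and 2 rose [18 and 2], and snoRNA host genes, where 10 of 26 fell and 2 rose [11 and 2]. These 3 sets had an adjusted p of 1.87e-25, 0.00169 and 0.0106, and with an estimated correlation 0.0746, 0.325 and 0.18. Of the monocyte and granulocyte genes 16 of 34 rose and 2 fell [18 and 2]. Of the lysosome genes 17 of 38 rose and 2 fell [21 and 2]. Of the histone genes 15 of 34 rose and 1 fell [16 and 2]. These had an adjusted p of 0.000217, 5.91e-06 and 0.00153, and with an estimated correlation 0.0779, 0.083 and 0.383.

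**Figure D3:**
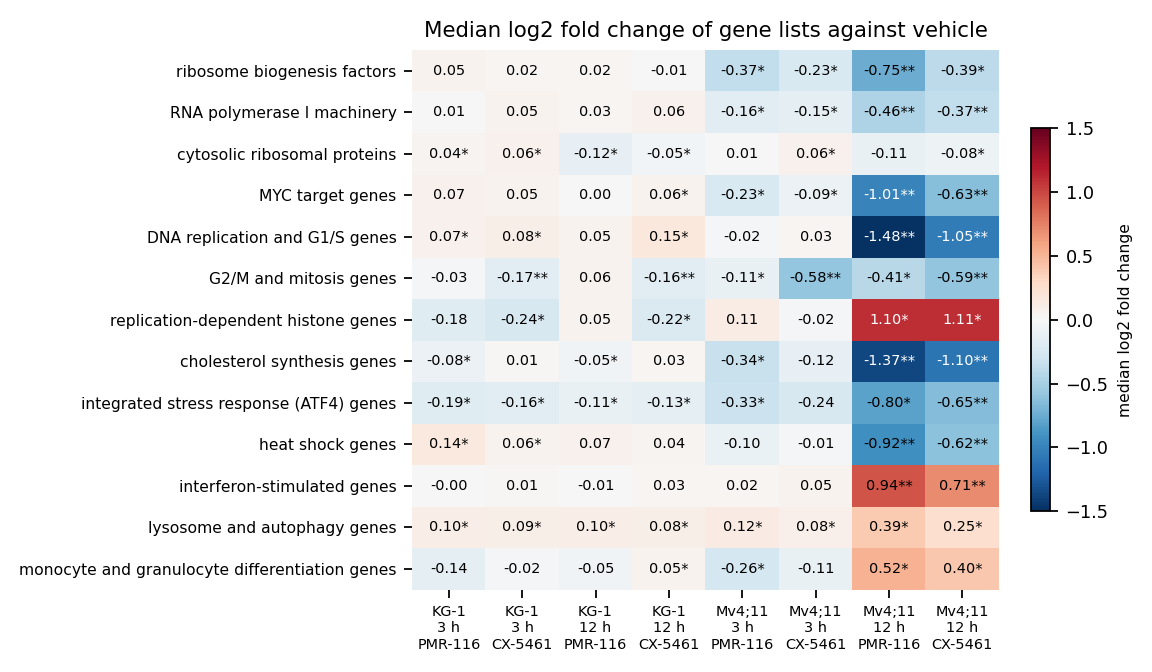
Median log2 fold change against vehicle of the tested members of 13 gene lists (one line each) in the 8 comparisons (one column each), with a colour scale that ends at ±1.5. A single asterisk marks a camera adjusted p under 0.05 and a double asterisk one that also holds with an estimated correlation, as for the DNA replication genes at 12 h in Mv4;11 (medians -1.48 and -1.05).

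After 3 h of PMR-116 in KG-1, CDKN1A and MDM2 were not called and MYC fell slightly (n = 4 per group). The rises were led by FAM222A (1.27 ± 0.12), the potassium channel KCNJ14 (1.24 ± 0.11), the adaptor CARD9 (1.07), the xenobiotic-metabolising CYP1A1 (0.99 ± 0.20), DMPK (0.95), the stress transcription factor ATF5 (0.86), HEXIM1 (0.85 ± 0.05), an inhibitor of the elongation factor P-TEFb, and LNPK (0.81). The falls were led by TIGD5 (-1.92 ± 0.11), the succinate receptor SUCNR1 (-1.19), SLC19A1 (-1.08 ± 0.11), the cannabinoid receptor CNR2 (-0.99), MDM4 (-0.95 ± 0.18), the corepressor CBFA2T3 (-0.90), STON2 (-0.89) and FCGR1B (-0.86). CDKN1A stood at 3.35 ± 0.999 against 2.57 ± 0.700 CPM (0.39 ± 0.24, adjusted p = 0.383) and MDM2 at -0.15 ± 0.06 (adjusted p = 0.161). MYC fell (-0.30 ± 0.09, adjusted p = 0.0429) and RRN3 rose by 0.17 (adjusted p = 0.0473), and both calls ended without 1 library (any 1 library but treated 2, 0.137 for MYC and any 1 library but treated 2, vehicle 3, 0.126 for RRN3). POLR1A (-0.05) and UBTF (-0.01) were not called (adjusted p = 0.788 and 0.945). Of the ribosome biogenesis factors 2 of 106 rose and 1 fell [1 and 1]. Of the RNA polymerase I machinery 1 of 21 rose and 0 fell [0 and 0], and neither was called as a set (adjusted p = 0.308 and 0.423, brackets adjusted over the list alone). Of the DNA replication genes 6 of 56 rose and 0 fell [12 and 1], including cyclin E1, CCNE1 (0.60). Of the heat shock genes 5 of 23 rose and 0 fell [7 and 0], including HSPA1A (0.61). Of the lysosome genes 6 of 37 rose and 0 fell [6 and 0]. Of the stem cell and leukaemia genes 4 of 29 fell and 0 rose [6 and 1], including CDK6 (-0.25) and LMO2 (-0.46). Of the mitochondrial mRNAs 5 of 13 fell and 1 rose [5 and 1]. These 5 sets had an adjusted p of 0.000134, 0.000134, 0.000389, 0.00508 and 0.00547, and with an estimated correlation an adjusted p of 0.775, 0.764, 0.419, 0.419 and 0.775. In all, 10 of 25 lists were called and 0 with an estimated correlation. Ribosome biogenesis factors were called without vehicle replicate 1 (adjusted p = 0.014).

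CX-5461 for 3 h in KG-1 lowered mitotic genes (n = 4 per group). The rises were led by KCNJ14 (0.99 ± 0.11), FAM222A (0.97), RAB40B (0.83), the adenylate cyclase ADCY9 (0.77), MAP3K6 (0.71), GLIS2 (0.70), MYORG (0.69) and KLHL26 (0.69). The falls were led by TIGD5 (-0.88 ± 0.11), SUCNR1 (-0.81), FCGR1B (-0.80), CNR2 (-0.79), the mitotic gene DEPDC1 (-0.73), MDM4 (-0.73), the centriole gene HYLS1 (-0.71) and GPR65 (-0.71). Calls that ended without 1 library were FCGR1B (treated 2, vehicle 2, 0.0828), GLIS2 (treated 1 and 2, 0.076), MAP3K6 (treated 1 and 3, vehicle 2 and 4, 0.105) and MDM4 (treated 1 and 2, vehicle 2, 0.0847). CDKN1A was at 0.62 ± 0.24 (adjusted p = 0.165) and MYC at -0.08 ± 0.09 (adjusted p = 0.732). Of the G2/M genes, 20 of 65 fell and 0 rose [30 and 0], including KIF20A (-0.48) and HJURP (-0.43), which loads the centromeric histone (adjusted p = 5.81e-21, and adjusted p = 0.0141 with an estimated correlation, brackets adjusted over the list alone). Of the DNA replication genes 10 of 56 rose and 0 fell [20 and 0], including CCNE1 (0.61) and CCNE2 (0.65). Of the immediate-early genes 3 of 33 rose and 0 fell [3 and 0]. Of the lysosome genes 4 of 37 rose and 0 fell [5 and 1]. These 3 sets had an adjusted p of 1.17e-09, 8.2e-05 and 0.00142, and with an estimated correlation 0.352, 0.349 and 0.349. In all, 9 of 25 lists were called and 1 of them, the G2/M genes, with an estimated correlation too. Not called were ribosome biogenesis factors, where 1 of 106 fell and 0 rose [1 and 0], and the RNA polymerase I machinery, where 0 of 21 rose and 0 fell [0 and 0] (adjusted p = 0.807 and 0.13). The RNA polymerase I machinery was called without vehicle replicate 1 (adjusted p = 0.0268). In this comparison log2 fold changes also fell with gene length across 9645 genes (Spearman rho = -0.28, 1 of 12 such correlations computed), and rho was -0.214 between the vehicle groups of the same line and time. Genes are not independent replicates.

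At 12 h of PMR-116 in KG-1 (n = 4 per group), the largest rises were CYP1A1 (1.62 ± 0.21), the cadherin CELSR2 (1.08), ATF5 (1.07), MAP3K6 (1.05), the polyamine enzyme SAT1 (1.01 ± 0.06), granzyme A, GZMA (0.96), DMPK (0.93) and ZDHHC11 (0.91). The falls were led by PGK2 (-1.31 ± 0.12), the interleukin 33 receptor gene IL1RL1 (-1.08), COL18A1 (-1.03), SEMA4A (-1.03), TMEM135 (-1.01), CDK6-AS1 (-0.97), MDM4 (-0.95) and RGL4 (-0.92). CDK6-AS1 is antisense to CDK6 and uncertain. CDKN1A was at 0.64 ± 0.24 (adjusted p = 0.0919), MYC at -0.16 ± 0.09 (adjusted p = 0.325) and UBTF fell (-0.19, adjusted p = 0.04). Calls that ended without 1 library were UBTF (treated 3 and 4, vehicle 1, 2 and 4, 0.169), TMEM135 (treated 1, 3 and 4, vehicle 2, 0.0748) and ZDHHC11 (vehicle 1 and 2, 0.0536), and CDKN1A was called without treated replicate 1 (adjusted p = 0.0474). Of the cytosolic ribosomal protein genes, 25 of 78 fell and 0 rose [33 and 0], with a median of -0.12 and RPL13 at -0.32 ± 0.05 (adjusted p = 1.36e-12, and adjusted p = 0.804 with an estimated correlation, brackets adjusted over the list alone). In all, 8 of 25 lists were called and 0 with an estimated correlation, and 6 of the 8 lost the call without some library. Not called were ribosome biogenesis factors, where 6 of 106 rose and 4 fell [6 and 4], the RNA polymerase I machinery, where 2 of 21 rose and 2 fell [2 and 2], and G2/M genes, where 11 of 65 rose and 5 fell [12 and 5] (adjusted p = 0.254, 0.582 and 0.0585). Of these, ribosome biogenesis factors were called without vehicle replicate 1 or treated replicate 3 (adjusted p at most 0.0119) and G2/M genes without treated or vehicle replicate 4 (0.0455).

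CX-5461 for 12 h in KG-1 lowered mitotic genes (n = 4 per group). The rises were led by MAP3K6 (1.10 ± 0.19), the catenin CTNND1 (1.07 ± 0.20), the fatty acid receptor FFAR2 (0.94), DTX4 (0.88), PELI3 (0.81), SPAG1 (0.80), GZMA (0.80) and the pentraxin PTX3 (0.77). The falls were led by CDC42EP2 (-1.01), BANK1 (-0.84), the chromatin remodeller CHD2 (-0.75 ± 0.11), the kinesins CENPE (-0.68) and KIF20A (-0.65 ± 0.07), TTC28 (-0.67), SMTN (-0.65) and the histone gene H2BC12 (-0.64). CDKN1A rose by 0.96 ± 0.24 (adjusted p = 0.0224), from a level of only 2.29 ± 0.671 CPM in the vehicle, and MYC was at -0.10 ± 0.09 (adjusted p = 0.741). Calls that ended without 1 library were CDKN1A (treated 3 and 4, vehicle 1 and 2, 0.0978), CDC42EP2 (treated 1 and 4, vehicle 2 and 3, 0.177), DTX4 (treated 2, vehicle 2 and 4, 0.0803), PTX3 (treated 2, vehicle 3, 0.053) and CSF1 (treated 1 and 2, vehicle 1 and 3, 0.0942). Of the G2/M genes 22 of 65 fell and 0 rose [34 and 0], including PLK1 (-0.46) and CDC20 (-0.48). Of the NF-kB and cytokine genes 2 of 30 rose and 0 fell [8 and 0], including CSF1 (0.80). Of the DNA replication genes 16 of 56 rose and 0 fell [28 and 0], including thymidine kinase TK1 (0.30) (brackets adjusted over the list alone). These 3 sets had an adjusted p of 3.16e-25, 2.14e-07 and 1.35e-22, and with an estimated correlation an adjusted p of 0.00275, 0.00222 and 0.0677. In all, 13 of 25 lists were called and 2 of them with an estimated correlation too. Not called were ribosome biogenesis factors, where 2 of 106 rose and 0 fell [2 and 0] (adjusted p = 0.931). These were called in opposite directions without treated (adjusted p = 0.0116, lower) and vehicle replicate 1 (0.0186, higher).

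The compounds were compared with each other at the same dose and time, as the difference of their effects. In Mv4;11 at 3 h, 275 genes differed, 125 with a more positive and 150 with a more negative effect of PMR-116. CDKN1A was raised less by PMR-116 (difference of log2 fold changes -0.94, 95% interval -1.19 to -0.69, adjusted p = 0.000359), as was MDM2 (-0.93, 95% interval -1.25 to -0.62), and MYC was lowered more (-0.51, 95% interval -0.77 to -0.26, adjusted p = 0.0451). The call of MYC ended without 1 library (any 1 library but CX-5461 2, PMR-116 1, 0.152). NECTIN4 (-2.67, 95% interval -3.38 to -1.95) and the interleukin receptor IL21R (-1.60) were among the most negative differences and SLFN5 (1.57) among the most positive. POLR1A (-0.21, 95% interval -0.43 to 0.01) and POLR1B (-0.45, 95% interval -0.76 to -0.14) were not called (adjusted p = 0.453 and 0.189). Among G2/M genes 33 of 66 had a positive difference and 0 a negative one [52 and 1], brackets adjusted over the list alone, with a median of 0.46 (adjusted p = 6.86e-72, and adjusted p = 0.00249 with an estimated correlation). Among mitochondrial mRNAs 6 of 13 had a negative difference and 0 a positive one [10 and 1] (adjusted p = 2.11e-15, and adjusted p = 0.139 with an estimated correlation). The count of 275 became 143 to 172 without PMR-116 vehicle replicate 3 (143) or 2, CX-5461 vehicle replicate 1 or 3, or replicate 3 of either compound, and 458 without PMR-116 replicate 1.

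In Mv4;11 at 12 h, 1047 genes differed between the compounds, 260 with a more positive and 787 with a more negative effect of PMR-116 (571 and 550 with library totals in place of TMM). POLR1A was lowered more by PMR-116 (-0.70, 95% interval -0.93 to -0.48, adjusted p = 0.00064), as were MYC (-0.60, 95% interval -0.85 to -0.35, adjusted p = 0.0063) and SLC38A5 (-1.72, 95% interval -2.04 to -1.41), and MDM2 was raised less (-0.58, 95% interval -0.89 to -0.26), a call that ended without 1 library (CX-5461 1 and 3, CX-5461 vehicle 2 and 3, PMR-116 1 and 2, PMR-116 vehicle 1 and 3, 0.114). CDKN1A was not called (-0.20, 95% interval -0.45 to 0.05, adjusted p = 0.451). Among the most positive differences was DNASE2 (2.24, 95% interval 1.66 to 2.81), and the most negative beside SLC38A5 were LIF (-2.17), UNC13A (-1.81) and the netrin receptor UNC5A (-1.78). Among DNA replication genes 34 of 56 had a negative difference and 0 a positive one [48 and 0], brackets adjusted over the list alone (adjusted p = 2.4e-48, and adjusted p = 0.0206 with an estimated correlation). Among MYC target genes 30 of 53 had a negative difference and 0 a positive one [38 and 0] (adjusted p = 2.48e-35, and adjusted p = 0.0206 with an estimated correlation). Among ribosome biogenesis factors 39 of 106 had a negative difference and 0 a positive one [67 and 0] (adjusted p = 1.12e-29, and adjusted p = 0.153 with an estimated correlation). Among mitochondrial mRNAs 10 of 13 had a negative difference and 0 a positive one [12 and 0] (adjusted p = 1.69e-21, and adjusted p = 0.0501 with an estimated correlation), and without the vehicle library that stood apart the adjusted p was 4.76e-38.

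In KG-1 at 3 h, 2 genes differed between the compounds, TIGD5 (-1.03, 95% interval -1.33 to -0.74, adjusted p = 0.00319) and AP5B1 (-0.51, 95% interval -0.67 to -0.36). At 12 h, 9 differed, including the mitotic gene DLGAP5 (0.70, 95% interval 0.45 to 0.95), SPPL2A (0.59) and the linker histone H1-10 (0.39) in the positive direction, and SYNE3 (-0.47), TSPAN33 (-0.46), the kinase PAK1 (-0.43) and SLA2 (-0.36) in the negative direction. The count of 9 fell to 0 without CX-5461 replicate 1 or 2, CX-5461 vehicle replicate 3, PMR-116 replicate 3 or 4 or PMR-116 vehicle replicate 4, to 1 without PMR-116 vehicle replicate 1, to 3 without CX-5461 vehicle replicate 2, and to 5 without CX-5461 replicate 4 or PMR-116 vehicle replicate 3. Each of the 7 named genes lost its call without at least 6 of the 16 libraries (adjusted p at most 0.116). CDKN1A (-0.23, 95% interval -0.89 to 0.44 at 3 h and -0.32, 95% interval -0.98 to 0.34 at 12 h), MYC (-0.22, 95% interval -0.48 to 0.04 and -0.07, 95% interval -0.32 to 0.19) and POLR1A (0.02, 95% interval -0.18 to 0.23 and -0.02, 95% interval -0.22 to 0.18) were not called. As a set, the G2/M genes had a more positive effect of PMR-116 than of CX-5461 at 12 h, where 1 of 65 had a positive difference and 0 a negative one [31 and 1], brackets adjusted over the list alone, with a median of 0.23 (adjusted p = 1.27e-33, and adjusted p = 0.000958 with an estimated correlation). At 3 h 0 of 65 had a positive difference and 0 a negative one [4 and 0], with a median of 0.14 (adjusted p = 2.45e-19, and adjusted p = 0.0215 with an estimated correlation).

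Genes changed by both compounds in one direction exceeded the overlap of independent lists. In Mv4;11 they were 693 higher and 1007 lower at 3 h (113.9 and 177.5 for independent lists), and 2364 higher and 2994 lower at 12 h (629.5 and 763.4). Opposite calls numbered 11 at 3 h and 21 at 12 h. In KG-1 they were 228 higher and 175 lower at 3 h (12.5 and 10.9 for independent lists), and 160 higher and 120 lower at 12 h (12.0 and 10.4), with 0 and 1 opposite. The Spearman correlation of the fold changes across genes, which are not independent replicates, was 0.474 and 0.656 in Mv4;11 and 0.414 and 0.329 in KG-1. No library served both compounds.

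**Figure D4:**
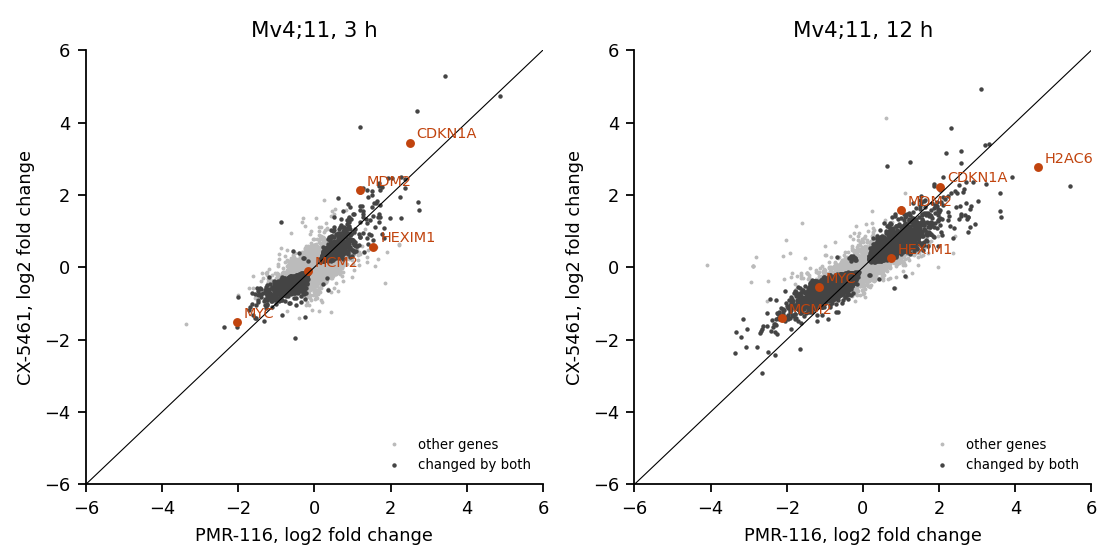
Log2 fold changes of CX-5461 (vertical) against those of PMR-116 (horizontal) in Mv4;11 at 3 h and 12 h, for genes at 5 CPM or more in either compound's group or in the vehicle for PMR-116. Black dots were changed by both compounds (adjusted p under 0.05), grey dots were not, the line marks equality, and the named genes include CDKN1A at 2.50 and 3.44 at 3 h.

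The effects at 12 h and 3 h were compared to ask how the response moved with time. In Mv4;11, 5659 genes differed between the times for PMR-116 (2493 more positive at 12 h, 3166 more negative) and 3430 for CX-5461 (1555 and 1875). With library totals in place of TMM these were 3592 and 2247, and 2061 and 1495. UNC13A (4.33 ± 0.50 for PMR-116 and 4.41 ± 0.45 for CX-5461), H2AC6 (4.15 and 3.39) and HMOX1 (3.62 and 2.90) moved upwards with time. UNG (-2.80 ± 0.12), ALDH1L2 (-2.67), the neuropeptide GAL (-2.62) and FADS2 (-2.62) moved downwards for PMR-116, and BAIAP3 (-4.34), PHGDH (-2.68), DDIT4 (-2.19) and AK4 (-2.16) for CX-5461. The fall of MYC was smaller at 12 h (0.87 ± 0.13 and 0.96 ± 0.13), as was the rise of CDKN1A (-0.48 ± 0.13 and -1.22 ± 0.13), while POLR1A fell further with PMR-116 (-0.55). All 56 DNA replication and G1/S genes moved downwards with time for both compounds, also adjusted over the list alone (adjusted p = 6.34e-132, and adjusted p = 0.000242 with an estimated correlation for PMR-116, adjusted p = 1.2e-115, and adjusted p = 0.000511 with an estimated correlation for CX-5461). Among cholesterol synthesis genes for PMR-116 24 of 29 had a negative difference and 1 a positive one [25 and 2], brackets adjusted over the list alone (adjusted p = 4.67e-19, and adjusted p = 0.0222 with an estimated correlation). Among interferon-stimulated genes 19 of 42 had a positive difference and 0 a negative one [21 and 0] (adjusted p = 6.53e-08, and adjusted p = 0.0222 with an estimated correlation). Among MYC target genes 43 of 53 had a negative difference and 1 a positive one [45 and 1] (adjusted p = 1.87e-37, and adjusted p = 0.0106 with an estimated correlation). For CX-5461, among interferon-stimulated genes 14 of 42 had a positive difference and 0 a negative one [17 and 0] (adjusted p = 6.51e-08, and adjusted p = 0.0233 with an estimated correlation).

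In KG-1, 314 genes differed between the times for PMR-116 (171 more positive at 12 h, 143 more negative) and 49 for CX-5461 (27 and 22). TIGD5 (1.99 ± 0.15 for PMR-116 and 1.02 ± 0.15 for CX-5461) moved upwards with time, as did FCGR1B for PMR-116 (1.27), and KCNJ14 (-1.23 and -1.58) moved downwards, as did FAM222A for CX-5461 (-1.13). The count of 49 became 22 to 32 without 3 h treated replicate 1 (22) or 2, 12 h treated replicate 1 or 4, 3 h vehicle replicate 1, 3 or 4, or 12 h vehicle replicate 3. Genes changed in one direction at both times in Mv4;11 were 1125 higher and 1515 lower for PMR-116 (466.2 and 605.2 for independent lists, 461 opposite), and 506 higher and 676 lower for CX-5461 (153.8 and 223.8, with 163 opposite). In KG-1 they were 189 higher and 153 lower for PMR-116 (31.8 and 32.7, with 11 opposite), and 45 higher and 43 lower for CX-5461 (4.7 and 3.5, with 3 opposite).

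The effects were compared between Mv4;11 and KG-1 in a joint fit of 23759 genes. PMR-116 effects differed for 1650 genes at 3 h (891 more positive in Mv4;11, 759 more negative) and 6027 at 12 h (2884 and 3143), and CX-5461 effects for 730 (373 and 357) and 3854 (1705 and 2149). At 3 h RLE factors gave 732 and 1026 for PMR-116 and 335 and 486 for CX-5461, and at 12 h library totals gave 3895 and 2572 for PMR-116 and 2164 and 1887 for CX-5461. CDKN1A rose more in Mv4;11 with PMR-116 (2.13 ± 0.26 at 3 h, adjusted p = 6.15e-08, and 1.44 ± 0.25 at 12 h) and with CX-5461 (2.86 ± 0.25 and 1.30 ± 0.25). MDM2 gave differences of 1.40, 1.01, 2.29 and 1.67 in the same order, and MYC -1.67 ± 0.14, -0.93, -1.40 and -0.43. POLR1A fell more in Mv4;11 with PMR-116 (-0.37, adjusted p = 0.0361, and -0.93), and with CX-5461 its differences of -0.15 ± 0.11 and -0.28 ± 0.11 were not called (adjusted p = 0.633 and 0.0952). Without 1 library the calls of MYC for CX-5461 at 12 h (KG-1 treated 2, KG-1 vehicle 3, Mv4;11 treated 3, 0.0734) and of POLR1A for PMR-116 at 3 h (KG-1 treated 1, Mv4;11 treated 3, 0.0574) ended, and POLR1A was called for CX-5461 at 12 h (KG-1 treated 2 and 3, KG-1 vehicle 1 and 4, Mv4;11 vehicle 2, 0.0496). All 56 DNA replication genes had a more negative effect in Mv4;11 at 12 h of either compound, also adjusted over the list alone (adjusted p = 7.59e-109, and adjusted p = 1.05e-05 with an estimated correlation for PMR-116, adjusted p = 5.43e-129, and adjusted p = 2.15e-06 with an estimated correlation for CX-5461). Among ribosome biogenesis factors at 12 h of PMR-116, 92 of 106 had a negative difference and 1 a positive one [98 and 1], brackets adjusted over the list alone (adjusted p = 2.98e-43, and adjusted p = 0.0212 with an estimated correlation). Some of the largest single differences, such as ADM (-7.63 ± 1.89 for PMR-116 at 12 h), lay in genes near 0 in one of the lines, and their sizes are imprecise.

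Genes changed in one direction in both lines were 326 higher and 313 lower at 3 h of PMR-116 (80.4 and 95.2 for independent lists over 16424 genes, 56 opposite) and 293 higher and 362 lower at 12 h (184.8 and 218.7, with 353 opposite). For CX-5461 they were 79 higher and 116 lower at 3 h (18.4 and 21.1, with 12 opposite) and 77 higher and 80 lower at 12 h (38 and 40.6, with 75 opposite). Each line was sequenced in its own batch, so line and batch cannot be told apart. No gene differed between the vehicle groups of the 2 compounds at either time in either line with edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 838 and 479 such genes in KG-1 and 762 and 858 in Mv4;11, at 3 h and 12 h, and DESeq2 called 2 and 1 in KG-1 and 1 and 0 in Mv4;11. Without a filter on low counts edgeR called 0 at both times in KG-1 but 126 at 3 h and 174 at 12 h in Mv4;11, and with only the groups compared in the fit 1 at each time in KG-1. At 12 h in Mv4;11, 17 genes differed without PMR-116 vehicle replicate 1 and 13 without replicate 2, fits in which the library that stood apart was 1 of 2.

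Mitochondrial RNAs of the heavy strand changed with their position. In KG-1, PMR-116 raised MT-RNR1 (chrM, GRCh38, 648 to 1601) by 0.66 ± 0.08 at 3 h and 0.83 ± 0.08 at 12 h, and MT-ND1 (3307 to 4262) by 0.53 ± 0.12 and 0.67 ± 0.12. It lowered MT-ND4 (10760 to 12137), at -0.35 ± 0.07 and -0.51 ± 0.07, and MT-CYB (14747 to 15887), at -0.59 ± 0.10 and -0.82 ± 0.10. In Mv4;11, MT-RNR1 was at 1.37 ± 0.43 at 3 h (adjusted p = 0.0221), a call that ended without vehicle replicate 2 or 3 or treated replicate 3 (highest adjusted p 0.0821). At 12 h it was at 0.09 ± 0.42 (adjusted p = 0.884), and at 1.73 ± 0.11 without the vehicle library that stood apart (adjusted p = 2.26e-11). PMR-116 raised MT-RNR2 (1671 to 3229) by 0.88 ± 0.11 and 0.94 ± 0.11 in that line and lowered MT-CYB, at -0.95 ± 0.10 and -1.35 ± 0.10. Counts of MT-ND6 (14149 to 14673, light strand, strand setting unknown) were at -0.12 ± 0.18 and 0.20 ± 0.18 in KG-1 (adjusted p = 0.747 and 0.567) and fell in Mv4;11, at -0.48 ± 0.11 and -1.02 ± 0.11 (adjusted p = 0.00191 and 4.1e-08). Each listed gene encodes a mitochondrial ribosomal RNA or a respiratory chain subunit. Across the 14 heavy-strand genes, Spearman's rho between position and log2 fold change was -0.974 and -0.991 for PMR-116 at 3 h and 12 h in KG-1, and -0.873 and -0.921 in Mv4;11. The adjusted permutation p, over the family of 8 such correlations, was 2.67e-05 for 3 of these (raw p of 1e-05, the smallest that 100000 draws can give) and 0.000224 for Mv4;11 at 3 h. For CX-5461 rho was -0.807 and -0.815 in KG-1 and -0.653 and -0.913 in Mv4;11 (adjusted permutation p = 0.00096, 0.00096, 0.0138 and 8e-05). Genes are not independent replicates. The slope was -0.094 and -0.12 log2 units per kb for PMR-116 in KG-1, -0.147 and -0.152 in Mv4;11, and for CX-5461 -0.027 and -0.039 in KG-1 and -0.03 and -0.088 in Mv4;11. The slopes of all treated libraries were below those of their own vehicle libraries in all 8 comparisons, with an exact permutation p of 0.0286 with 4 libraries per group and 0.1 with 3, the smallest possible for each size. Between the vehicle groups rho was 0.16 and 0.09 in KG-1 and 0.108 at 3 h in Mv4;11, but -0.886 at 12 h in Mv4;11, where the vehicle for PMR-116 held the library with high MT-RNR1. On means of log2 CPM, that rho was -0.903 with and -0.56 without this library, and the rho of PMR-116 against vehicle -0.93 with and -0.952 without it.

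**Figure D5:**
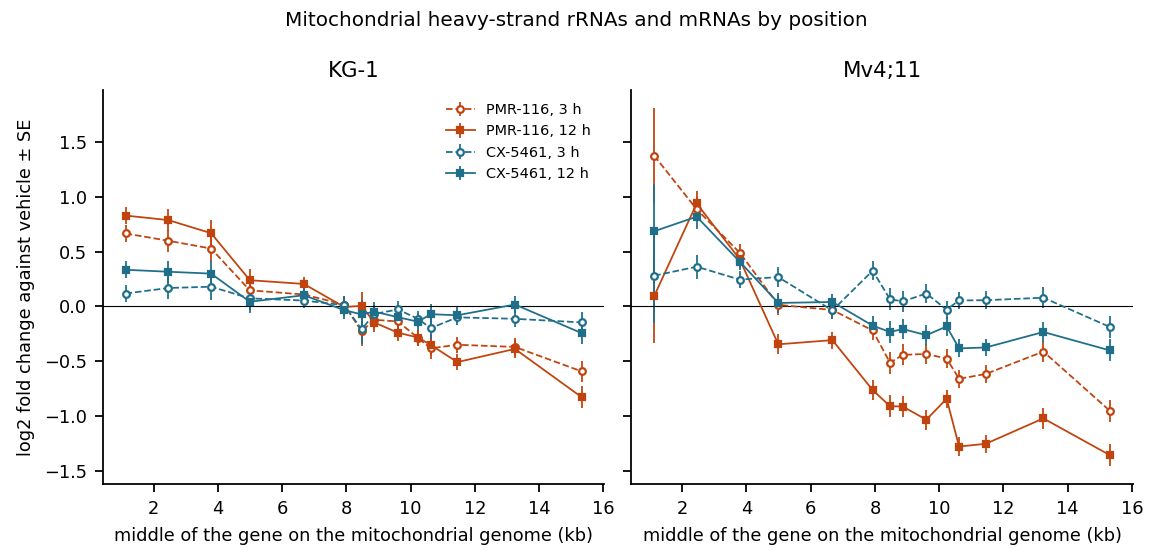
Log2 fold change against vehicle (± SE) of 14 mitochondrial heavy-strand genes, in order of the middle of the gene on the mitochondrial genome in kb, for PMR-116 (orange) and CX-5461 (blue) at 3 h (open, dashed) and 12 h (filled, solid). The fold change fell from MT-RNR1 to MT-CYB, with a slope of -0.12 log2 units per kb for PMR-116 at 12 h in KG-1.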

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

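The test of batch in the first pattern, the tests of single libraries and of the light-strand gene in the second, and the test of the longest genes in the third were chosen only after the result was seen. The first pattern is the larger response of Mv4;11, where the median size of the log2 fold change over genes well expressed in both lines was 0.17 and 0.315 for PMR-116 at 3 h and 12 h against 0.097 and 0.106 in KG-1, and 0.125 and 0.229 against 0.086 and 0.077 for CX-5461. Lower precision in KG-1 is argued against, since the median standard error in KG-1 was at most 0.91 times that in Mv4;11. A batch effect cannot be told apart from the line, because 0 of the deposited tables held libraries of both, and a biological difference between the lines stays open, untested apart from it.

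The second pattern is the fall of mitochondrial heavy-strand RNAs with position under PMR-116, where without the 2 ribosomal RNAs rho was -0.958 and -0.986 in KG-1 and -0.797 and -0.895 in Mv4;11. Against a trend that merely varies between libraries, the slopes of all PMR-116 libraries lay below those of all vehicle libraries of the same line and time, with a smallest gap of 0.078 log2 units per kb, while for CX-5461 the gaps were 0.016, 0.003, 0.014 and -0.059 (the last 0.068 without the vehicle library that stood apart). RNA level and length are argued against by partial rank correlations of change with position given each (-0.919 and -0.935, Mv4;11 12 h). A candidate, less heavy-strand transcript reaching its far end, does not predict the fall of light-strand MT-ND6 in Mv4;11 (-0.48 and -1.02, MT-ND5 -0.41 and -1.02). MT-ND6 relative to MT-ND5 and MT-CYB was higher in all treated than all vehicle libraries in Mv4;11 (gaps 0.12 and 0.07, owing to MT-CYB) and at 12 h in KG-1 (0.38, and -0.38 at 3 h). Heavy-strand reads may count as MT-ND6 (strand setting unknown), so the candidate cannot be told apart from others. PMR-116 vehicles of Mv4;11 held 614 and 565 CPM of MT-ND6 (KG-1 71.7 and 56.4). RNA stability and capture were not tested.

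The third pattern is the fall of long genes, with a rho of -0.28 across 9645 genes after 3 h of CX-5461 in KG-1 and, among 231 genes longer than 300 kb, 23 that fell and 0 that rose, but also with 20 and 1 (3 h) and 58 and 3 (12 h) for PMR-116 and 17 and 0 for CX-5461 at 12 h in KG-1, and 39 and 2 for PMR-116 and 35 and 4 for CX-5461 at 3 h in Mv4;11 (51 and 57, and 32 and 49, at 12 h). For the correlation, the length of the spliced RNA and a low level of long genes are argued against by partial correlations with gene length of -0.208 and -0.283. A length trend that varies between libraries is in line with the values, since the vehicle groups of that line and time differed with a rho of -0.214 and those of Mv4;11 at 3 h with -0.251. Length slopes of single treated and vehicle libraries overlapped (exact permutation p = 0.0571, with 0.0286 the smallest possible for 4 against 4), so an effect of CX-5461 cannot be claimed from the correlation across all genes. As the whole cause of the falls of the longest genes such a trend is argued against, since their median level was lower in all 4 treated than in all 8 vehicle libraries of that time (gap 0.038 log2 units, and 0.007 to 0.041 in the other 5 comparisons, those of Mv4;11 at 12 h left out) and their median difference between the vehicle groups was -0.007 against -0.108 for CX-5461, and an effect on them stays open.

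Other splits of the same libraries were fitted for each count. In KG-1 only the real split (1 of 35) gave as many genes in each comparison with vehicle. Counts were 1364, 640, 1762 and 473 for PMR-116 and CX-5461 at 3 h and then 12 h (highest other 11, 1, 4 and 1). Other splits put any effect into the spread, so chance is not excluded. In Mv4;11 the 10 splits are too few (4939, 2390, 8859 and 6430 real, highest other 0 each time). The vehicle groups gave 0 genes in the real split, as few as any of the 35 splits in KG-1 (highest other 1 at each time), and the 10 in Mv4;11 are too few (highest other 1 and 4).

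Differences between groups drew attention because the test of the difference itself called genes. Between the compounds, 2 genes differed at 3 h and 9 at 12 h in KG-1, and chance cannot be excluded (5 and 4 of 40 splits gave as many, highest other 34 and 476). At 3 h all 4 other splits with as many genes parted the treated libraries of both compounds by replicate number (4 of 9 such splits), which points to a structure of the samples that follows the number. At 12 h the split with 476 did so (1 of 6), but the 2 further ones with as many genes did not (highest 330), so the number alone does not account for them. With the number as a block 18 and 179 genes differed. In Mv4;11, 275 and 1047 genes differed and chance cannot be excluded by 40 splits (5 and 7 gave as many, highest other 460 and 1726), but where the treated libraries of each compound were also divided the highest was 28 and 2. Between the times, only the real split (1 of 40) gave as many as the 314 genes with PMR-116 and 49 with CX-5461 in KG-1 (highest other 163 and 2). The same held for 3430 with CX-5461 in Mv4;11 (highest other 3406), but not for 5659 with PMR-116 (2 of 40, highest other 6442). Between the lines it held for 6027 genes with PMR-116 at 12 h (1 of 30 splits, highest other 5904). It did not for 1650 with PMR-116 at 3 h (5 of 30, highest other 3097) or 730 and 3854 with CX-5461 at 3 h and 12 h (4 and 3 of 30, highest other 1568 and 4388). These splits exchanged treated and vehicle labels within each time or line. A split that kept the labels of 1 time or line carried its effect into the difference. They therefore cannot decide whether chance gave these differences of effects. Splits with as many genes between the lines mostly kept the labels of the Mv4;11 libraries, and where those were divided the highest was 235 and 4 for PMR-116 and 5 and 2 for CX-5461.

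In 9 of 232 sets of 4 KG-1 libraries, 1 library lay far from the others, where chance alone gives about 1 in 20. At 12 h, CX-5461 vehicle replicate 4 had 24790 genes with a count (others 24050 to 24100) and CX-5461 vehicle replicate 1 had SPAG1 at 4.198 CPM (3.608 to 3.701). At 3 h, CX-5461 replicate 3 had 6.48% of its counts in its top 10 genes (6.32 to 6.34). The 5.8S ribosomal RNA was at 46.4 CPM in CX-5461 vehicle replicate 3 (32.28 to 32.99) and 113 CPM in CX-5461 replicate 3 (20.58 to 31.22) at 12 h. At 3 h of PMR-116, vehicle replicate 2 had MDM4 at 41.01 CPM (30.67 to 32.35) and treated replicate 2 had RRN3 at 74.59 CPM (82.72 to 83.88). At 12 h of PMR-116, replicate 2 had TMEM135 at 6.675 CPM (3.693 to 4.179) and replicate 1 had MDM4 at 22.22 CPM (24.61 to 24.88).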

How the results depend on the processing

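Scaling by library totals, and leaving out the Mv4;11 vehicle library that stood apart, were alternatives chosen after the data were seen, and the others were set beforehand. With RLE factors no count of genes moved by more than 1.5 times, all 710 results of named genes in the comparisons with vehicle kept their direction and their side of the threshold, and 184 of 185 results of named differences did (1 was newly called). Library totals ended 24 of the 710 and 7 of the 185 results, the fit without a filter on low counts 46 and 7, the fit of only the groups compared 89 and 32, and DESeq2 0 of 707 and 0 of 185, and none of these 4 settings reversed one. Among 508 gene list results, called or not, an estimated correlation ended most calls (167). Fry, which asks another question, ended 68, library totals 12 and RLE factors 1. None reversed. CDKN1A in KG-1, at 2.57 ± 0.700 CPM, had a standard error of its log2 fold change of 0.24 against 0.10 in Mv4;11.

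Counts that moved by more than 1.5 times are given here by setting, each against the count in the report, and the cause was not tested unless stated. Without a filter on low counts, genes changed in KG-1 were 371 against 640 for CX-5461 at 3 h, 268 against 473 at 12 h, and 1152 against 1762 for PMR-116 at 12 h. In that fit the compounds differed for 3 genes against 9 at 12 h in KG-1 and 714 against 275 at 3 h in Mv4;11, the times in KG-1 for 171 against 314 (PMR-116) and 23 against 49 (CX-5461), and the vehicle groups of Mv4;11 for 126 against 0 at 3 h and 174 against 0 at 12 h. With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, the KG-1 counts were 332 (CX-5461 at 3 h), 911 (PMR-116 at 12 h) and 71 (CX-5461 at 12 h). The compounds then differed for 1 gene at 3 h, which was neither of the 2 in the report, and 0 at 12 h in KG-1 and 139 at 3 h in Mv4;11, the times for 162 and 8 in KG-1, and the vehicle groups of KG-1 for 1 gene at each time. DESeq2 called 1105 and 803 genes for CX-5461 at 3 h and 12 h in KG-1. It called 16 and 91 differences between the compounds in KG-1, 608 and 1581 in Mv4;11, 631 and 195 between the times in KG-1, 1154 for CX-5461 at 3 h between the lines, and 2 and 1 between the vehicle groups in KG-1 and 1 at 3 h in Mv4;11. Library totals gave 26 differences between the compounds at 12 h and 83 between the times for CX-5461 in KG-1.

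Treated and vehicle libraries with the same replicate number deviated from their group means with correlations of 0.024 to 0.238 in KG-1, all 16 above 0 and 9 above 0.1, and of -0.013 to 0.11 in Mv4;11, 1 of 12 above 0.1. No comparison had all above 0.1, so libraries were not paired. Treated libraries correlated best with their own number in 13 of 16 cases in KG-1 and 10 of 12 in Mv4;11. KG-1 samples were numbered in replicate order, so pairing there is open. With the replicate number as a block, the KG-1 counts rose to 2599 and 1733 at 3 h and 3198 and 1313 at 12 h for PMR-116 and CX-5461, and those of Mv4;11 were 5270, 2705, 9097 and 6722. Differences became 18 and 179 between the compounds in KG-1, 1235 and 402 between the times in KG-1, 1220 between the lines for CX-5461 at 3 h, and 1 between the vehicle groups at 3 h in Mv4;11. The block ended no call of a named gene and newly called 5 of the 710 results against vehicle and 6 of the 185 differences. Among these were CDKN1A and MYC in KG-1 (above) and RRN3 for PMR-116 at 3 h in Mv4;11 (adjusted p = 0.0435). UBTF was called between the times (0.0133 in KG-1 and 0.0398 in Mv4;11 for PMR-116, 0.0331 in Mv4;11 for CX-5461). POLR1A was called between the lines for CX-5461 at 12 h (0.0259). Of the 508 results of lists it ended 3 and newly called 5.

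Leaving out each library in turn gave, at 3 h and 12 h, 901 to 1279 and 1191 to 1513 genes for PMR-116 in KG-1, 362 to 582 and 288 to 401 for CX-5461 in KG-1, 3461 to 4710 and 7879 to 8375 for PMR-116 in Mv4;11, and 1573 to 1948 and 5294 to 6040 for CX-5461 in Mv4;11. Between the compounds it gave 2 to 3 and 0 to 13 in KG-1 and 143 to 458 and 724 to 1084 in Mv4;11. Between the times it gave 218 to 306 (PMR-116) and 22 to 50 (CX-5461) in KG-1 and 5039 to 5590 and 2798 to 3474 in Mv4;11. Between the lines it gave 1199 to 1962 and 5475 to 6164 for PMR-116 and 538 to 825 and 3157 to 4583 for CX-5461. Between the vehicle groups it gave 0 throughout, except for 0 to 17 at 12 h in Mv4;11. Fewer libraries were tested in each of these fits. Omissions ended 119 of 710 and 51 of 185 named gene results and 47 of 508 for lists. Lists that held with an estimated correlation stayed called with the preset, the only one rerun. Reversed were 4 differences between the lines, each no longer called then (adjusted p = 1). DYSF for PMR-116 at 12 h ran from -6.21 to 0.58 (without Mv4;11 vehicle replicate 3), and for CX-5461 SFT2D3 at 3 h from -8.74 to 0.56 (vehicle replicate 1), P2RY14 at 12 h from 5.96 to -0.01 (treated replicate 1) and FEV at 12 h from -5.68 to 0.05 (vehicle replicate 3). Lists not called in the report that were called in the other direction were ribosome biogenesis factors for CX-5461 at 12 h in KG-1 (adjusted p = 0.0116 to 0.863, and 0.0186 without vehicle replicate 1) and ribosomal proteins between the lines for PMR-116 at 3 h (0.000695 to 0.925, with the lowest without vehicle replicate 1 and 0.00456 without treated replicate 3 of Mv4;11). The cause of these was not tested.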

Other observations

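The genes of this part were picked out after their values were seen, except where the naming rule took them, and no test was chosen for them beyond the comparisons of the report. HEXIM1 rose after 3 h in Mv4;11 with PMR-116 (1.55 ± 0.08) and CX-5461 (0.57 ± 0.08) and at 12 h (0.74 ± 0.08 and 0.25 ± 0.08). In KG-1 it rose after 3 h (0.85 ± 0.05 and 0.59 ± 0.05) and with PMR-116 at 12 h (0.29 ± 0.05), and with CX-5461 at 12 h it was at 0.11 ± 0.05 (adjusted p = 0.395). JARID2, a subunit associated with Polycomb repressive complex 2, was lower in all 4 KG-1 comparisons (-0.29 and -0.33 at 3 h, -0.42 and -0.30 at 12 h, PMR-116 first), and in Mv4;11 at 12 h it was higher (0.54 ± 0.07 and 0.31 ± 0.07). CYP1A1 rose with PMR-116 in both lines (0.99 ± 0.20 and 1.62 ± 0.21 in KG-1, 1.14 ± 0.30 and 2.80 ± 0.32 in Mv4;11) and with CX-5461 at 12 h in Mv4;11 (1.11 ± 0.31).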
